A study of Rattus norvegicus with 18 samples.

How the data were processed

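RNA from rat spinal cord material was measured on 18 single-channel Affymetrix expression arrays. Per the labels, 6 arrays were controls, 6 were of material given 10 ng/mL of bone morphogenetic protein (BMP) and 6 of material given 10 ng/mL of ciliary neurotrophic factor (CNTF), each of these 12 with the entry "4d", read here as 4 days. The label of the controls gives no such time, so it is not known whether they were taken at the same time as the arrays they are compared with, and every difference against control carries this limit. The entry "14 NT", which opens the description of all 18 arrays, the treated ones included, was not interpreted. The labels name neither the BMP family member nor the cell type or culture, and give no growth, extraction or labelling protocol. Each title also carries a number from 1 to 6 that occurs once in every group; arrays are named here by group and number. Nothing in the labels says that arrays of 1 group came from separate cultures or animals, so p-values measure the spread between these arrays, which may be partly technical.

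The deposited values were linear probe set intensity values between 0.404 and 162940, with 31099 probe sets per array and no value missing. The summary method, its version and the scaling target are not given in the sources used here. After 2% of the values had been trimmed at each end, the mean intensity lay between 2500.7 and 2500.8 on all 18 arrays, a property of the deposited values that a global scaling to 1 target gives. The 75th percentiles of the arrays ranged over 0.0696 on the log2 scale. That was below the limit of 0.3 set for quantile normalization, so the deposited normalization was kept. The median intensity per array was 666.5 to 817.2. For arrays, the number of arrays per group limits the precision; no counts or depths exist.

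Values were analysed as log2(intensity + 116.655), the constant being the 20th percentile of the whole table. Log2 differences, and the fold values and the 2-fold limit taken from them, are therefore on this scale. They understate the change of dim genes. The median of the table, 746.4, corresponds to 9.75. The 57 Affymetrix control probe sets were left out, which left 31042 probe sets for testing. Gene names came from the platform annotation, with identifiers matched to current rat RefSeq genes. Of the tested probe sets, 20826 carried 1 gene symbol, 436 carried several and 9780 carried none. No symbol was changed by the match. Probe sets with several symbols or none were counted and not named. In total 14217 genes were named. A gene was represented by its brightest probe set over all 18 arrays, and disagreement with other probe sets is stated where it arose.

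Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, group means, empirical Bayes moderation with an intensity trend) to all 18 arrays together, so that the 3 groups shared 1 estimate of the spread. Contrasts were BMP against control, CNTF against control, and BMP against CNTF. Tests were two-sided with Benjamini-Hochberg adjustment over all probe sets, and a probe set was called at an adjusted p under 0.05. A smaller class also required a change of at least 2-fold. Standard errors given after ± for log2 differences are limma's moderated standard errors; group values are the mean ± SD of 6 arrays.

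For gene groups, 25 lists with 475 different symbols, of which 432 were measured, were tested with camera (limma) at its preset correlation of 0.01, adjusted over the 25 lists within a contrast. The lists covered targets of BMP-SMAD and gp130-STAT3 signalling, interferon genes, markers of neural, glial, vascular, mesenchymal and immune cells, reactive astrocyte genes, cell cycle and its inhibitors, FGF-MAPK feedback, proteoglycans, matrix, axon guidance, neurotrophic factors, glutamate uptake, cholesterol synthesis, hypoxia, stress and the Notch pathway. Camera was repeated with the correlation estimated from the data, and its p, adjusted in the same way, is given as the estimated-correlation p. Members were counted as risen or fallen over all genes tested and, separately, adjusted over the list alone. The contrasts, lists, tests, most alternative settings and the rule for naming genes were fixed before the data were examined. By that rule, the genes named per contrast were the 5 with the largest rise and the 5 with the largest fall among called genes whose groups did not overlap and whose higher mean was at or above the median of the table, up to 4 members with the smallest adjusted p of each list that passed camera, and 16 genes always (Gfap, Aqp4, Slc1a3, S100b, Id1, Id3, Socs3, Stat3, Pdgfra, Cspg4, Olig2, Mbp, Nes, Ncan, Dcn and Mki67). Other genes named were chosen after their values were seen, as members of the lists or, in the closing section, as called genes.

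The title numbers were checked for pairing before the fits were compared. Deviations from the group means of arrays with the same number correlated in all 18 such pairs, with r between 0.121 and 0.491 (median 0.327) across probe sets, each over the limit of 0.1. The 90 pairs of arrays from different groups with different numbers had r between -0.399 and 0.357, median -0.0915. Every one of the 18 arrays correlated best with an array of its own number. The numbers were therefore taken to pair the arrays. The main test stayed without the pairing, as planned, and a fit with the number as a replicate block was run beside it.

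RNA and array quality was compared between groups with exact two-sided permutation tests of 7 measures per array (3'/5' ratios of the actin, GAPDH and hexokinase control probe sets, median and 75th percentile, and the hybridization and poly-A spike controls). None of the 21 tests passed Benjamini-Hochberg adjustment; the smallest adjusted p was 0.545. The smallest p before adjustment was that of the median, 0.0976 log2 higher in BMP than in control arrays (exact permutation p = 0.026), and the largest shift was in the hexokinase 3'/5' ratio, 0.173 log2 higher in BMP than in CNTF arrays (exact permutation p = 0.331). These tests ignore the title numbers. In a test added after the data had been examined, labels were exchanged within same-numbered pairs. The difference then had the same sign in 6 of 6 pairs for 4 of the 21 comparisons: the median and the 75th percentile (0.0976 and 0.0207 log2 higher in BMP than in control arrays), the GAPDH 3'/5' log2 ratio (BMP minus control -0.0306) and the median between BMP and CNTF arrays (0.0633 higher with BMP). Each had an exact permutation p of 0.03125, the smallest that 6 pairs can give, and an adjusted p of 0.164.

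The code was tested on simulated arrays with 67, 67 and 66 probe sets changed by 0.58, 1 and 2 log2 among 31042, drawn from those at or above the median, and with number effects as estimated from the data. For BMP against control, the fit without the block recovered 41.8%, 80.6% and 98.5% of them in that order; the fit with the block recovered 79.1%, 91.0% and 100%. The fit without the block made 0 false calls there and the fit with it 13. For BMP against CNTF the fit without the block recovered 40.3%, 83.6% and 98.5% with 0 false calls, and the fit with the block 77.6%, 94.0% and 100% with 14. Because both additions were compared with the same 6 control arrays, the agreement of their effects was set beside 100 simulations of unchanged groups against those controls and beside 20 ways of splitting the controls into sets of 3.

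Alternatives tried were the block, quantile normalization, a common 75th percentile, a filter on dim probe sets, constants of 1 and of the median in the log2 scale, no intensity trend, array weights, only the 2 groups compared, leaving out probe set types open to cross-hybridization, other probe sets of a gene, the mean of all probe sets of a gene, and each array left out in turn. Leaving out all 3 arrays of 1 number was added after the data had been examined. Tables were prepared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.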

Results

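Gene expression was measured in rat spinal cord material on 18 Affymetrix arrays, 6 of them controls. BMP, a secreted ligand of the TGF-beta family, had been given at 10 ng/mL to the material of 6 arrays, and the remaining 6 were of material given 10 ng/mL CNTF, a cytokine that signals through gp130 and STAT3. The labels put both additions at 4 days and give no time for the controls, so it is not known here whether the controls were taken at the same time. The comparisons asked which genes differed between each addition and the controls, and between the additions. The deposited values were linear intensities scaled to nearly equal trimmed means, and the median intensity of single arrays lay between 666.5 and 817.2. Levels are given as log2(intensity + 116.655), mean ± SD of 6 arrays. Fold values are ratios on this scale, with the constant included, and understate the change of dim genes. The first principal component held 18.99% of the variance and the second 16.5%. On the first, the BMP array was the highest of the 3 arrays with its title number in 6 of 6 cases. The numbers differed there too: BMP arrays 1 to 3 lay at 56.9 to 66.5 and BMP arrays 4 to 6 at 1.58 to 18.7. On the second, arrays of numbers 4 and 5 lay at 16.8 to 54.8 in every group, and the other arrays at -53.6 to 17.3. On the third (11.95%), the CNTF array was the lowest with its number in every case.

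With CNTF, genes of the gp130-STAT3 response and of reactive astrocytes rose. Spp1, which encodes the secreted phosphoprotein osteopontin, rose from 9.60 ± 1.15 to 16.62 ± 0.20, a difference of 7.02 ± 0.47 log2 or 129-fold (limma adjusted p = 2.4e-08). Gfap, the astrocyte intermediate filament, rose from 12.36 ± 2.51 to 16.32 ± 0.27 (+3.96 ± 0.78, adjusted p = 0.00708). Socs3, a feedback inhibitor of STAT3 signalling, rose from 8.87 ± 0.37 to 12.04 ± 0.39 (9.03-fold, adjusted p = 3.15e-09). Igf2, an insulin-like growth factor, rose 82.3-fold to 15.66 ± 0.45 (+6.36 ± 0.60, adjusted p = 3.07e-06), and H19, a non-coding RNA from the same imprinted locus, rose by 5.73 ± 0.53 (adjusted p = 2.27e-06). Each of these genes was higher with CNTF in 6 of 6 same-numbered pairs.

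Of 20 measured gp130-STAT3 targets, 11 rose and 0 fell with CNTF (13 rose and 1 fell adjusted over the list alone, camera adjusted p = 9.51e-20). Cebpd, a transcription factor of the acute phase response, rose by 3.78 ± 0.19 (adjusted p = 2.93e-10) and the protease inhibitor A2m by 4.36 ± 0.33 (adjusted p = 1.54e-07). The immediate early gene Fos rose by 3.20 ± 0.31 (adjusted p = 3.9e-06) and Stat3 itself by 1.11 ± 0.19 (adjusted p = 0.0021). Of 21 reactive astrocyte genes, 9 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 3.82e-14). Among them were the small heat shock protein Hspb1 (+6.26 ± 0.60, adjusted p = 3.5e-06) and the complement inhibitor Serping1 (+3.32 ± 0.34, adjusted p = 9.15e-06). The hyaluronan receptor Cd44 rose (+1.88 ± 0.32, adjusted p = 0.00191), as did Cd14, a lipopolysaccharide co-receptor (+1.48 ± 0.28, adjusted p = 0.00552). These lists, gp130-STAT3 targets and reactive astrocyte genes, were the calls in this comparison that held with an estimated correlation (adjusted p = 0.000122 and 0.000272). The 8 genes named so far in this paragraph were higher in 6 of 6 pairs. A second Cebpd probe set differed by 0.01 and a second Fos probe set by -0.31, neither of them called.

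Crym, a cytosolic thyroid hormone-binding protein, was the remaining gene among the 5 largest rises with CNTF (+4.72 ± 0.51, adjusted p = 1.45e-05). The 5 largest falls were those of Papss2, which makes the sulfate donor PAPS (-1.85 ± 0.34, adjusted p = 0.004), the cytokine Il33 (-1.84 ± 0.31, adjusted p = 0.00211), the transcriptional coactivator Ppargc1a, the GABA-A receptor subunit Gabrb1 and the melanosome protein Pmel. The last 3 differed by -1.79 ± 0.15, -1.67 ± 0.24 and -1.43 ± 0.35 (adjusted p = 9.43e-07, 0.000333 and 0.0348). Each was lower in 6 of 6 pairs. A second Papss2 probe set gave -1.44 (adjusted p = 0.053). The Pmel call was lost when 1 array was left out (adjusted p in brackets): control 2, 3 or 4 (0.0872, 0.0808 and 0.0536) or CNTF array 1, 2, 3, 4, 5 or 6 (0.0544, 0.0719, 0.0557, 0.0666, 0.0743 and 0.0619). Igf2 rested on 1 probe set: its 3 other probe sets lay between 7.21 and 7.74 with CNTF and differed from the controls by -0.15, -0.02 and 0.16.

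**Figure D1:**
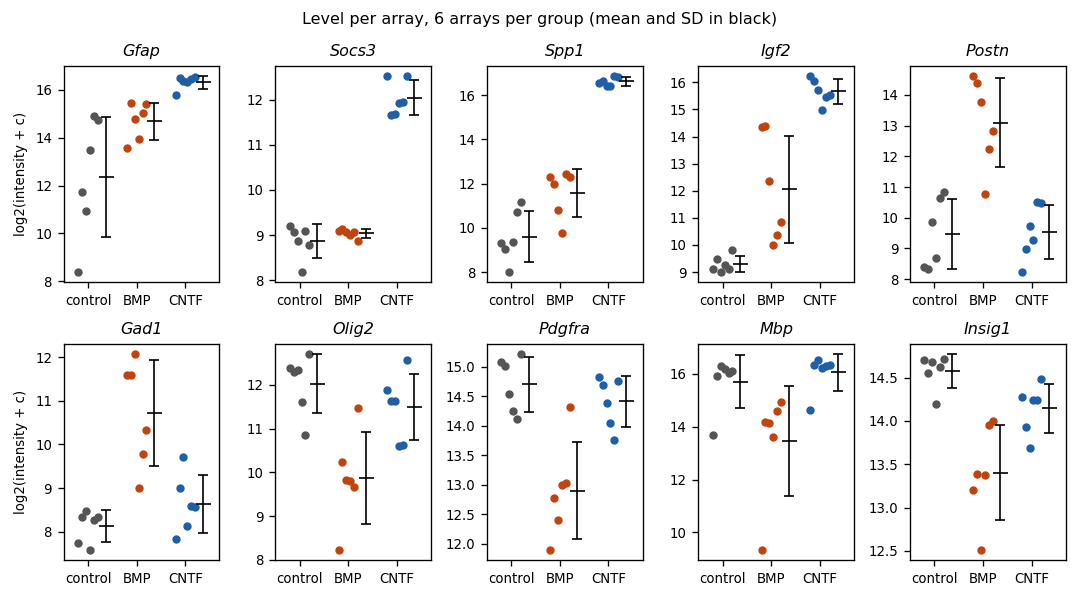
Levels of 10 genes on the log2(intensity + 116.655) scale in control, BMP and CNTF arrays, with a separate vertical axis per gene. Coloured dots are the 6 arrays of a group in the order of their title numbers, and black marks with bars are the mean and SD. Spp1 lay at 16.62 ± 0.20 with CNTF against 9.60 ± 1.15 in the controls, and Olig2 at 9.87 ± 1.05 with BMP against 12.03 ± 0.68.

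CNTF did not move most other groups past the threshold. No oligodendrocyte marker was called by limma (0 of 17, and 0 at an unadjusted p under 0.05, list adjusted p = 0.245). Mbp, a major myelin protein, was at 16.06 ± 0.70 against 15.71 ± 0.999 (+0.36 ± 0.71, adjusted p = 0.944). It was higher with CNTF in every same-numbered pair. The Mbp difference was -0.05 without control 1 and 0.64 without CNTF array 1. With the replicate block, the oligodendrocyte list passed upward (adjusted p = 0.0401, 2 members risen, estimated-correlation p = 0.705), and without the block it passed when CNTF array 1 (0.0158) or control 3 (0.0324) was left out (estimated-correlation p = 0.904 with all arrays). Of 11 precursor markers 1 rose, the tetraspanin Cd9 (+1.39, list adjusted p = 0.555, 1 rose and 2 fell with the block). Pdgfra, Cspg4 and Olig2, genes of oligodendrocyte precursors, differed by -0.29 ± 0.31, -0.56 ± 0.25 and -0.54 ± 0.44, and none was called (adjusted p = 0.85, 0.398 and 0.762). Each was nevertheless lower with CNTF in every same-numbered pair. Pdgfra ranged from -0.41 (without control 5) to -0.16 (without CNTF array 5). Cspg4 was called with the block (adjusted p = 0.0193). The cholesterol biosynthesis list passed camera downward (median -0.34, adjusted p = 5.14e-07, estimated-correlation p = 0.715) although 0 of its 16 members was called by limma over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 9 were lower. With the block 5 fell.

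In the CNTF comparison the 24 astrocyte markers went both ways. Gfap and Clu rose (+3.96 and +2.24) and the acyl-CoA synthetase Acsbg1 fell (-1.60), while 6 rose and 4 fell adjusted over the list alone and 7 rose and 5 fell with the block. The median was -0.04, the mean +0.27 and camera adjusted p = 0.897. Aqp4, the water channel of astrocyte endfeet, differed by 1.91 ± 0.62 (adjusted p = 0.147) and was called with the block (adjusted p = 0.000311) and without CNTF array 1 (0.0487). Slc1a3, S100b, Nes and Ncan differed by 0.42 ± 0.17, -0.06 ± 0.35, -0.26 ± 0.22 and -0.66 ± 0.32 and were not called (adjusted p = 0.323, 0.984, 0.784 and 0.458). Slc1a3 was higher with CNTF in every same-numbered pair, while S100b, Nes and Ncan went both ways. When any 1 array was omitted, S100b ranged from -0.22 (without CNTF array 6) to 0.14 (without CNTF array 1) and Nes from -0.42 (without CNTF array 1) to -0.10 (without control 1). The BMP target genes Id1 and Id3 differed by -0.52 ± 0.30 and -0.16 ± 0.26 (adjusted p = 0.572 and 0.921, Id3 from -0.27 without CNTF array 6 to -0.03 without CNTF array 3), and of 19 BMP-SMAD targets 0 were called by limma (2 rose and 1 fell with the block, 1 rose adjusted over the list alone, 3 higher and 1 lower at an unadjusted p under 0.05, list adjusted p = 0.897).

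For the other lists with CNTF, the Notch pathway had 1 fallen of 19, Nrarp at -1.35 (5 fallen adjusted over the list alone, adjusted p = 0.201). It passed downward with the block (adjusted p = 0.048, estimated-correlation p = 0.558) and without CNTF array 1 (0.0159) or control 5 (0.0307, estimated-correlation p = 0.715 with all arrays). Of 19 hypoxia and glycolysis genes, Ndrg1 and Pfkfb3 rose (+1.95 and +0.73). The mean was +0.05, the median -0.17, and camera, pointing down, gave an adjusted p of 0.623 without and 0.048 with the block (estimated-correlation p = 0.705 with the block). Among 17 stress genes Atf3 rose (+1.72, list adjusted p = 0.388, mean +0.18 and median -0.004), among 24 interferon genes Irf9 rose (+0.62, 0.32, and 0.0234 with dim probe sets left out, estimated-correlation p = 0.904 with all probe sets) and among 12 Schwann cell markers Pmp2 rose (+1.29, 0.245). Among 21 matrix genes Fn1 rose (+1.49, 0.32, 3 rose and 2 fell adjusted over the list alone), and among 17 neurotrophic factors Igf2 was the 1 that rose (0.422, 2 rose and 1 fell adjusted over the list alone). Cd44 rose and Cspg5 fell (-0.74) among 19 proteoglycan genes (list adjusted p = 0.32, 1 rose and 2 fell adjusted over the list alone). Slc7a11 rose (+1.92) and Slc6a9 fell (-1.07) among 15 glutamate uptake genes (0.268), and Sox3 fell (-1.21) among 14 neural stem cell markers (0.387). No member was called among 20 neuron markers (adjusted p = 0.387, 3 rose and 1 fell adjusted over the list alone), 12 cyclin-dependent kinase inhibitors (0.245, 3 rose adjusted over the list alone), 19 axon guidance genes (0.859, 1 rose adjusted over the list alone, median -0.11, mean +0.03), 15 FGF-MAPK feedback genes (0.897), or 12 endothelial markers (0.32). The same held for 17 microglia and macrophage markers (0.897), 17 fibroblast and smooth muscle markers (0.245, and 0.0375 without CNTF array 1) and 33 cell cycle genes (0.388, and 0.0187 and 0.0228 without controls 4 and 5). The estimated-correlation p of the last 2 lists was 0.904 and 0.943 with all arrays. At an unadjusted p under 0.05, limma had 4 neuron markers higher and 1 lower, 4 kinase inhibitors, 2 endothelial and 2 fibroblast markers higher, 2 guidance genes higher and 3 lower, and 0 genes of the FGF-MAPK, microglia and cell cycle lists. With the block, 4 neuron markers rose and 1 fell, 3 guidance genes rose and 3 fell, and 2 kinase inhibitors and 1 fibroblast marker rose. The block also gave 5 fallen Notch genes, 3 risen and 4 fallen hypoxia genes, 3 risen stress and 4 risen interferon genes, and 1 risen and 1 fallen Schwann cell marker. Risen and fallen members with the block were 4 and 3 for matrix genes, 2 and 2 for neurotrophic factors, 1 and 3 for proteoglycan genes, 2 and 4 for glutamate uptake and 1 and 2 for neural stem cell markers. The fibroblast gene Dcn and the proliferation marker Mki67 differed by 0.43 ± 0.32 and 0.39 ± 0.72 (adjusted p = 0.73 and 0.937). With 1 array left out, Dcn ranged from 0.27 (without CNTF array 2) to 0.63 (without CNTF array 1) and Mki67 from -0.27 (without control 3) to 0.76 (without control 5). Microglia markers were at most at 9.06 with CNTF, all below the table median of 9.75.

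Over all probe sets, limma called 721 for CNTF against control, 492 higher and 229 lower, and 353 of them by at least 2-fold (285 higher, 68 lower). They covered 433 named genes and 203 unnamed probe sets. With the block, 2349 were called, 1300 higher and 1049 lower, so that the share of higher calls went from 68.2% to 55.3%. All 721 were among them in the same direction. In settings added after the data had been examined, the count was 389, 420, 366 and 406 without all arrays of number 2, 3, 5 and 6.

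With BMP, 9 of 11 oligodendrocyte precursor markers, 10 of 17 oligodendrocyte markers and 15 of 16 cholesterol synthesis genes fell, while 5 of 21 matrix genes rose. These list calls were lost with an estimated correlation (estimated-correlation p = 0.0835, 0.121, 0.0835 and 0.095). Olig2, a transcription factor of oligodendrocyte precursors, fell from 12.03 ± 0.68 to 9.87 ± 1.05, 4.46-fold (-2.16 ± 0.44, limma adjusted p = 0.00536). Pdgfra, the receptor for PDGF-A on these cells, fell from 14.70 ± 0.46 to 12.90 ± 0.82 (-1.80 ± 0.31, adjusted p = 0.00162). Insig1, a sterol-regulated protein, fell from 14.58 ± 0.20 to 13.40 ± 0.55 (-1.18 ± 0.20, adjusted p = 0.0014). Postn, which encodes the matrix protein periostin, rose 12.4-fold from 9.46 ± 1.14 to 13.10 ± 1.46 (+3.64 ± 0.61, adjusted p = 0.00145). In numbers 1 to 6 the Postn rise was 6.24, 6.04, 3.88, 2.09, 1.59 and 1.98. Gad1, the enzyme that makes GABA, rose 6.10-fold from 8.12 ± 0.37 to 10.73 ± 1.22 (+2.61 ± 0.43, adjusted p = 0.0014). All 5 moved the same way in 6 of 6 pairs. A second Olig2 probe set gave -0.20 and was not called.

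Of 11 oligodendrocyte precursor markers, 9 fell and 0 rose with BMP, over all genes and adjusted over the list alone (camera adjusted p = 2.89e-10, estimated-correlation p = 0.0835). Besides Olig2 and Pdgfra they included the proteoglycan Cspg4 (-1.40 ± 0.25, adjusted p = 0.00249), Sox6 (-0.89 ± 0.17, adjusted p = 0.0038) and Lhfpl3 (-1.24 ± 0.23, adjusted p = 0.00334). Of 17 oligodendrocyte markers, 10 fell and 0 rose (12 and 0 adjusted over the list alone, adjusted p = 5.79e-10, estimated-correlation p = 0.121). Among these were the myelin enzyme Cnp (-1.35 ± 0.22, adjusted p = 0.00137) and Bcas1 (-1.44 ± 0.28, adjusted p = 0.00407). Gal3st1 and Ugt8, which make the myelin lipid sulfatide and its precursor, fell as well (-2.07 ± 0.35 and -1.90 ± 0.38, adjusted p = 0.00146 and 0.00512). A second Ugt8 probe set, at 7.12 in the controls, gave 0.07. Mbp went from 15.71 ± 0.999 to 13.46 ± 2.07 (-2.25 ± 0.71) and missed the threshold (adjusted p = 0.0679). It was called with the block (adjusted p = 0.000533), without control 1 (0.0325) or BMP array 6 (0.0423), and by 2 other Mbp probe sets (-1.95 and -2.64). Without BMP array 1, at 9.33 where the other 5 lay at 13.59 to 14.95, the Mbp difference was -1.42 (adjusted p = 0.0601). Dusp15, Dbndd2 and Tmem255b were among the 5 largest falls (-2.45 ± 0.45, -2.32 ± 0.35 and -2.38 ± 0.44, adjusted p = 0.00261, 0.00087 and 0.00304). The others were the cytochrome oxidase subunit Cox4i2 (-2.72 ± 0.50, adjusted p = 0.00284) and the lipase Pnlip (-2.28 ± 0.33, adjusted p = 0.000676).

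Of 16 cholesterol biosynthesis genes, 15 fell and 0 rose with BMP (all 16 fell adjusted over the list alone, camera adjusted p = 8.79e-21, estimated-correlation p = 0.0835). Lss, lanosterol synthase, fell by 1.11 ± 0.18 (adjusted p = 0.00114), Mvd, an enzyme of the mevalonate pathway, by 1.07 ± 0.17 (adjusted p = 0.00123) and Nsdhl, a sterol dehydrogenase, by 0.90 ± 0.15 (adjusted p = 0.00142). The list of 19 hypoxia and glycolysis genes also passed downward (median -0.46, adjusted p = 2.59e-05, estimated-correlation p = 0.342). Its 1 called member was the mitochondrial protein Bnip3 (-0.85 ± 0.24, adjusted p = 0.0385), and 9 fell adjusted over the list alone and 14 with the block. Of 15 genes of glutamate uptake and ion transport 3 fell, over all genes and over the list alone (7 with the block, adjusted p = 0.00368, estimated-correlation p = 0.158). They were the glutamate transporter Slc1a1 (-1.67 ± 0.30, adjusted p = 0.00225), the glycine transporter Slc6a9 (-1.25 ± 0.18, adjusted p = 0.000618) and the glutamine transporter Slc38a3 (-1.20 ± 0.33, adjusted p = 0.0369). The Bnip3 call was lost (adjusted p in brackets) without control 1, 4, 5 or 6 (0.0712, 0.0724, 0.0776 and 0.0858) or BMP array 1, 2 or 3 (0.058, 0.0996 and 0.0963). That of Slc38a3 was lost without control 1, 2, 4, 5 or 6 (0.053, 0.0649, 0.0802, 0.0802 and 0.0695) or BMP array 1, 2 or 3 (0.089, 0.0997 and 0.0935).

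**Figure D2:**
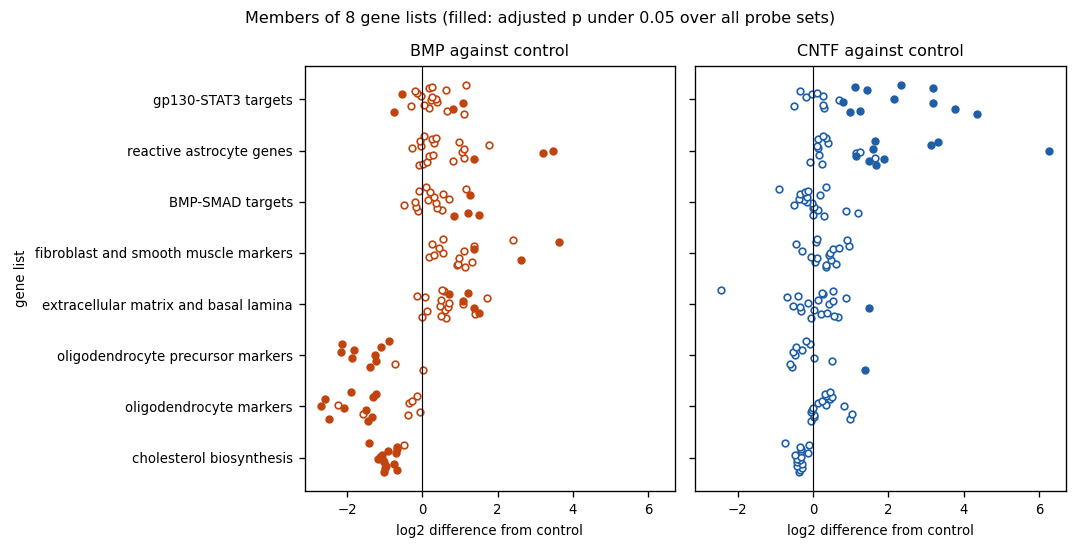
Log2 differences of the measured members of 8 gene lists, BMP against control on the left and CNTF against control on the right. Each point is 1 gene, filled where its adjusted p was under 0.05 over all probe sets. With BMP, 15 of 16 cholesterol biosynthesis genes and 9 of 11 oligodendrocyte precursor markers fell. With CNTF, 11 of 20 gp130-STAT3 targets rose.

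Of 21 genes of the matrix and basal lamina, 5 rose and 0 fell with BMP (14 and 0 with the block, 12 and 0 adjusted over the list alone, camera adjusted p = 4.63e-08, estimated-correlation p = 0.095). Sparc rose (+1.22 ± 0.18, adjusted p = 0.00082), with the laminin chain Lamb2 (+1.07 ± 0.14, adjusted p = 0.000407) and fibronectin, Fn1 (+1.36 ± 0.25, adjusted p = 0.00304). So did the collagen Col6a2 (+1.51 ± 0.32, adjusted p = 0.00677), of which a second probe set gave 0.61 (adjusted p = 0.244). Of 17 fibroblast and smooth muscle markers 3 rose and 0 fell (10 and 0 with the block, 8 and 0 adjusted over the list alone, adjusted p = 1.25e-06, estimated-correlation p = 0.158). They were Postn, the type I collagen chain Col1a2 (+2.61 ± 0.50, adjusted p = 0.00349) and the crosslinking enzyme Loxl1 (+1.36 ± 0.37, adjusted p = 0.0339). Dcn and Lum, proteoglycans of fibroblasts, were at 7.96 ± 0.58 and 7.68 ± 0.52 with BMP, below the table median, and Dcn did not pass (+0.31 ± 0.32, adjusted p = 0.694, from 0.17 without BMP array 2 to 0.51 without BMP array 1). Loxl1 lost its call (adjusted p in brackets) without control 1, 2, 3 or 4 (0.0548, 0.0503, 0.0806 and 0.079) or BMP array 1, 2, 3 or 6 (0.0747, 0.0925, 0.07 and 0.0603).

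Of 20 neuron markers, 4 rose and 1 fell with BMP (10 and 2 with the block, 9 and 1 adjusted over the list alone, camera adjusted p = 0.000845, estimated-correlation p = 0.325). The secretory granule protein Scg2 rose by 3.30 ± 0.56 (adjusted p = 0.0017) and the neurofilament Nefl by 0.95 ± 0.15 (adjusted p = 0.00125), while the neuronal RNA-binding protein Elavl3 fell by 0.50 ± 0.13 (adjusted p = 0.0222). Of 19 axon guidance genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, adjusted p = 0.0169, estimated-correlation p = 0.163). The secreted repellents Slit1 (+1.78 ± 0.25, adjusted p = 0.000535) and Sema3c (+2.52 ± 0.50, adjusted p = 0.00498) and the semaphorin receptor Nrp1 (+1.41 ± 0.24, adjusted p = 0.00178) rose, with Slit2 and Nrp2 (+1.04 and +1.03). The myelin glycoprotein Omg fell (-1.66 ± 0.34, adjusted p = 0.00639). Elavl3 lost its call (adjusted p in brackets) without control 3 or 5 (0.0537 and 0.0524) or BMP array 1 (0.0578), and its second probe set gave -0.43 (adjusted p = 0.0525).

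Of 19 BMP-SMAD targets, 4 rose and 0 fell with BMP (6 and 0 adjusted over the list alone, adjusted p = 0.00274, estimated-correlation p = 0.121). They were the pseudoreceptor Bambi (+1.502 ± 0.35, adjusted p = 0.0139), the BMP antagonist Nbl1 (+1.26 ± 0.19, adjusted p = 0.000997), the BMP-binding protein Bmper (+1.20 ± 0.34, adjusted p = 0.0404) and the transcription factor Atoh8 (+0.84 ± 0.22, adjusted p = 0.0295). Id1 and Id3, at 14.90 ± 0.28 and 15.68 ± 0.33 in the controls, differed by -0.50 ± 0.30 and -0.21 ± 0.26 (adjusted p = 0.406 and 0.755). When any 1 array was omitted, Id1 ranged from -0.65 (without BMP array 1) to -0.26 (without BMP array 3) and Id3 from -0.34 (without BMP array 1) to -0.05 (without BMP array 2). Bmper lost its call with quantile normalization (adjusted p = 0.0548), with the constant at the median (0.0719) and without control 1, 3, 4, 5 or 6 (0.0747, 0.0548, 0.075, 0.0524 and 0.0957) or BMP array 1, 2 or 3 (0.0603, 0.107 and 0.0928). Atoh8 lost it with quantile normalization (0.0663) and without control 3, 5 or 6 (0.0696, 0.0518 and 0.0562) or BMP array 1, 2 or 4 (0.0722, 0.0614 and 0.0554).

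Of 21 reactive astrocyte genes 3 rose and 0 fell with BMP (7 and 0 with the block, 5 and 0 adjusted over the list alone, adjusted p = 0.000446, estimated-correlation p = 0.0835). They were Hspb1 (+3.48 ± 0.60, adjusted p = 0.0018), the membrane protein Emp1 (+3.21 ± 0.43, adjusted p = 0.000489) and Cd44 (+1.38 ± 0.32, adjusted p = 0.0119, a second probe set 1.09, adjusted p = 0.0518). Of 24 astrocyte markers 2 rose, Aqp4 (+2.33 ± 0.62, adjusted p = 0.0295) and Nfia (+0.84, 6 rose and 1 fell with the block, 4 rose adjusted over the list alone, list adjusted p = 0.259). Gfap was at 14.69 ± 0.78 against 12.36 ± 2.51 and was not called (+2.33 ± 0.78, adjusted p = 0.0867). It was higher in 6 of 6 pairs, by 5.17, 3.69, 3.84, 0.44, 0.16 and 0.68 in numbers 1 to 6. Without control 1, at 8.39, the difference was 1.53 (adjusted p = 0.14). It was called with the block (adjusted p = 0.0169) and without control 5 (0.0305) or 6 (0.0392). The intermediate filament Nes differed by -0.73 ± 0.22 and was called with the block (adjusted p = 0.0515 and 0.000845), with a common 75th percentile (0.0451) and without control 3 (0.0325). Slc1a3, S100b and Ncan differed by -0.17 ± 0.17, 0.35 ± 0.35 and 0.02 ± 0.32 (adjusted p = 0.698, 0.679 and 0.985). When 1 array was left out, Slc1a3 ranged from -0.30 (without BMP array 4) to -0.06 (without BMP array 2), S100b from 0.18 (without BMP array 6) to 0.56 (without BMP array 4) and Ncan from -0.12 (without BMP array 6) to 0.24 (without BMP array 2). The remaining largest rises were the small heat shock protein Cryab (+3.42 ± 0.63, adjusted p = 0.0026) and the secreted protein Cytl1 (+3.32 ± 0.51, adjusted p = 0.000982). Aqp4 lost its call (adjusted p in brackets) without control 1 or 4 (0.0558 and 0.0659) or BMP array 2, 3, 5 or 6 (0.0711, 0.0608, 0.0532 and 0.0543).

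The gp130-STAT3 list did not pass with BMP (2 rose and 2 fell of 20, 6 and 2 with the block, 7 and 2 adjusted over the list alone, adjusted p = 0.0635). Fos and Cebpd rose (+1.08 and +0.82), Bcl3 and Myc fell (-0.75 and -0.53), and Socs3 and Stat3 differed by 0.17 ± 0.18 and 0.26 ± 0.19 (adjusted p = 0.698 and 0.522). When any 1 array was omitted, Socs3 ranged from 0.04 (without control 4) to 0.24 (without control 1) and Stat3 from 0.12 (without control 1) to 0.43 (without control 5). The list passed upward without BMP array 3 (0.0461), BMP array 4 (0.0197) or control 5 (0.0372), with dim probe sets left out (0.0175) and with the mean of all probe sets (0.0383). Its estimated-correlation p was 0.325. The 33 cell cycle genes had a median of +0.49 with 0 called (adjusted p = 0.0629, 0 members also adjusted over the list alone). They passed with the block (0.00367), with quantile normalization (0.0249), with dim probe sets left out (0.0403) and without controls 1, 4 or 5 or BMP array 1 or 3 (0.0197, 0.000651, 0.00097, 0.0374 and 0.00344). The estimated-correlation p of this list was 0.81 without and 0.685 with the block. Mki67 differed by 0.60 ± 0.72 (adjusted p = 0.744), and by -0.06 without control 3 and 0.97 without control 5. Of 19 proteoglycan genes 2 rose and 5 fell (3 and 6 adjusted over the list alone, adjusted p = 0.335), the rises being Cd44 and Spock1 (+1.76) and the falls including Cspg5 (-0.83) and Ptprz1 (-1.09). Of 17 neurotrophic factors 4 rose and 1 fell (5 and 2 adjusted over the list alone): Igf2 (+2.75), Nrtn (+2.27), Igf1 (+1.67), Mdk (+0.79) and Vegfa (-1.25). The median was -0.13, the mean +0.29 and the adjusted p 0.814. Of 19 Notch pathway genes, Dll4, Notch2 and Numb rose (+1.45, +0.65 and +0.48) and Nrarp and Hes5 fell (-1.69 and -1.57, adjusted p = 0.446). At a limma unadjusted p under 0.05, 3 Notch genes were higher and 4 lower. Prom1 rose (+1.02) and Hes5 fell among 14 neural stem cell markers (0.617, 2 rose and 3 fell adjusted over the list alone), and Nqo1 rose (+1.08) and Xbp1 fell (-0.30) among 17 stress genes (0.986, median -0.01, mean +0.08). Among the other lists, 1 member was called among 24 interferon genes (Ifi27, +0.80, 0.335), 12 Schwann cell markers (L1cam, +1.49, 0.335), 12 endothelial markers (Tek, +0.95, 0.611) and 15 FGF-MAPK feedback genes (Myc, 0.259, 3 rose and 1 fell adjusted over the list alone). None of 17 microglia and macrophage markers (adjusted p = 0.814) and none of 12 cyclin-dependent kinase inhibitors (0.986) was called by limma. At an unadjusted p under 0.05 these were 0 of the microglia markers, 1 inhibitor higher and 1 lower, and 0 of the cell cycle genes. With the block, 1 inhibitor rose and 2 fell, and 1 cell cycle gene fell. Risen and fallen members with the block were 5 and 3 for neurotrophic factors, 4 and 3 for neural stem cell markers, 2 and 2 for stress and for FGF-MAPK feedback genes and 2 and 1 for interferon genes, while 3 Schwann cell and 2 endothelial markers rose.

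Over all probe sets, limma called 1865 for BMP against control, 1067 higher and 798 lower, of which 743 changed at least 2-fold (522 higher, 221 lower). They covered 1121 named genes and 536 unnamed probe sets. With the block 5176 were called, 2824 higher and 2352 lower, and all 1865 were among them in the same direction. Without all arrays of number 2 the count was 740 (407 at least 2-fold) and without those of number 3 it was 1008, settings added after the data had been examined. The BMP effect was larger in numbers 1 to 3 than in numbers 4 to 6, by the slopes given further below. The means above therefore average over uneven numbers. None of the list calls for BMP against control held with an estimated correlation. The median of all values was higher in the BMP array than in the control array of the same number in 6 of 6 pairs, by 0.0976 log2, and the GAPDH 3'/5' log2 ratio was lower in 6 of 6, by a difference of -0.0306.

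Compared directly with CNTF, 12 of 17 oligodendrocyte markers and 8 of 20 gp130-STAT3 targets were lower with BMP (estimated-correlation p = 0.105 and 0.0019), and 7 of 21 matrix genes were higher (estimated-correlation p = 0.149). Spp1 was at 11.60 ± 1.08 with BMP and 16.62 ± 0.20 with CNTF (-5.02 ± 0.47, limma adjusted p = 3.35e-06), and Socs3 at 9.04 ± 0.09 and 12.04 ± 0.39 (-3.001 ± 0.18, adjusted p = 1.31e-08). Cldn11, the tight junction protein of myelin, was lower with BMP, at -3.46 ± 0.73 (adjusted p = 0.006), as was the myelin transcription factor Myrf, at -3.06 ± 0.55 (adjusted p = 0.00195). Postn was higher with BMP by 3.56 ± 0.61 (adjusted p = 0.00132) and Slit1 by 2.39 ± 0.25 (adjusted p = 1.03e-05). All 6 kept these directions in 6 of 6 pairs.

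Of 17 oligodendrocyte markers 12 were lower with BMP than with CNTF and 0 higher, over all genes and adjusted over the list alone (camera adjusted p = 4.81e-13, estimated-correlation p = 0.105, and 0.0309 with the block). Ugt8 was at -2.36 ± 0.38 (adjusted p = 0.000846, a second probe set 0.08), Gal3st1 at -2.06 ± 0.35 (0.00122), Cnp at -1.37 ± 0.22 (0.000896) and Mbp at -2.60 ± 0.71 (0.0328). Of 11 precursor markers 7 were lower (10 adjusted over the list alone, adjusted p = 8.45e-10, estimated-correlation p = 0.105). Among them were Lhfpl3 (-1.75 ± 0.23, adjusted p = 0.000143), Nkx2-2 (-1.90 ± 0.37, 0.00374), Cd9 (-1.36 ± 0.25, 0.0025), Pdgfra (-1.51 ± 0.31, 0.00475) and Olig2 (-1.62 ± 0.44, 0.0307, a second probe set -0.10). Cspg4 differed by -0.84 ± 0.25 (adjusted p = 0.0546) and was called with the block (0.000501), with quantile normalization (0.0411), with the constant at 1 (0.0483) and without BMP array 6 (0.00575). The Mbp call was lost (adjusted p in brackets) without CNTF array 2, 3, 4, 5 or 6 (0.0628, 0.0634, 0.0594, 0.0644 and 0.0693). That of Olig2 was lost without BMP array 1, 3 or 5 (0.0672, 0.0589 and 0.0591) or CNTF array 1, 2, 3 or 6 (0.0595, 0.0586, 0.0556 and 0.0834).

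Of 20 gp130-STAT3 targets 8 were lower with BMP and 0 higher (14 and 0 adjusted over the list alone, adjusted p = 2.56e-12), which was the list call in this comparison that held without the block with an estimated correlation (adjusted p = 0.0019). With the block, this list and the oligodendrocyte markers held (estimated-correlation p = 0.0212 and 0.0309). Cebpd differed by -2.96 ± 0.19 (adjusted p = 1.67e-08, a second probe set -0.14), A2m by -3.25 ± 0.33 (1.03e-05), Junb by -1.78 ± 0.21 (3.54e-05) and Stat3 by -0.85 ± 0.19 (0.009). Of 21 reactive astrocyte genes 4 were lower and 1 higher (5 and 1 adjusted over the list alone, adjusted p = 0.00202, estimated-correlation p = 0.121). Serping1 was at -2.35 ± 0.34 (adjusted p = 0.000349), Aspg at -1.78 ± 0.34 (0.00333), Hspb1 at -2.78 ± 0.60 (0.00736) and Emp1 at 2.07 ± 0.43 (0.00601). Igf2, through its 1 responding probe set, and the hyaluronan-binding protein Tnfaip6 were lower as well (-3.62 ± 0.60 and -3.26 ± 0.41, adjusted p = 0.00107 and 8.13e-05). For Igf2 the differences in numbers 1 to 6 were -1.90, -1.68, -3.36, -4.96, -5.11 and -4.68. Gfap differed by -1.63 ± 0.78 and was not called (adjusted p = 0.286, and 0.0957 with the block), although it was lower with BMP in 6 of 6 pairs and no BMP array (14.69 ± 0.78) reached the lowest CNTF array (16.32 ± 0.27). In numbers 1 to 6 Gfap differed by -2.22, -1.05, -1.60, -2.38, -1.39 and -1.12. The standard error rests on the spread shared by all 3 groups. For Gfap the controls, which are not compared here, spread the most. The missing call therefore does not show that Gfap was alike with both additions. Aqp4 differed by 0.42 ± 0.62 (0.829), with 0.04 and 0.25 without CNTF array 1 and 4 and 0.62 without BMP array 1.

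Matrix and basal lamina genes were higher with BMP than with CNTF in 7 of 21 cases and lower in 0 (10 and 1 with the block, 11 and 1 adjusted over the list alone, adjusted p = 5.68e-06, estimated-correlation p = 0.149). Among them were Sparc (+0.99 ± 0.18, adjusted p = 0.00245), Col6a2 (+1.14), the laminins Lama4 (+1.001 ± 0.22, 0.00775) and Lamb2 (+0.55 ± 0.14, 0.0211), and tenascin, Tnc (+2.97 ± 0.67, 0.0102). Of 17 fibroblast and smooth muscle markers 2 were higher, Postn and Col1a2 (+2.14 ± 0.50, 0.012, 5 with the block, 3 adjusted over the list alone, list adjusted p = 0.000508, estimated-correlation p = 0.354). Of 19 axon guidance genes 4 were higher and 1 lower (6 and 4 with the block, 5 and 2 adjusted over the list alone, adjusted p = 0.0108, estimated-correlation p = 0.149). Nrp1 and Nrp2 were at 1.20 ± 0.24 and 1.16 ± 0.23 (0.0046 and 0.00394, a second Nrp2 probe set 0.50), Rgma at 0.51 ± 0.11 (0.00723) and Omg at -1.49. Of 19 BMP-SMAD targets 3 were higher, Smad9 (+2.06 ± 0.35, 0.00132, a second probe set 0.48), Bambi (2.83-fold, 0.0131) and Nbl1 (+1.06 ± 0.19, 0.00226), and 0 lower (6 and 1 with the block and adjusted over the list alone, list adjusted p = 0.00419, estimated-correlation p = 0.149). The other largest differences with BMP higher were those of Ecrg4 (+3.61 ± 0.62, 0.00132), Cryab (+3.59 ± 0.63, 0.00151), Cytl1 (+3.59 ± 0.51, 0.000272) and Papss2 (+3.43 ± 0.34, 6.26e-06). Lamb2 lost its call (adjusted p in brackets) without BMP array 1 or 2 (0.0542 and 0.057) or CNTF array 4 (0.0526).

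Of 20 neuron markers 3 were higher with BMP and 2 lower (8 and 2 with the block, 6 and 2 adjusted over the list alone, adjusted p = 0.00617, estimated-correlation p = 0.42, adjusted p = 0.0527 without BMP array 3). Higher were Gad1 (+2.09 ± 0.43, adjusted p = 0.00547), the synaptic protein Snap25 (+1.01 ± 0.25, 0.0193) and Syt1 (+1.05), and lower were Elavl3 (-0.53 ± 0.13, 0.0159) and the growth cone protein Gap43 (-0.67 ± 0.17, 0.0195, a second probe set 0.12). Cholesterol genes were lower in 8 of 16 cases and higher in 0 (all 16 lower with the block and adjusted over the list alone, adjusted p = 8.1e-11, estimated-correlation p = 0.149). Lss was at -0.81 ± 0.18 (0.00835, a second probe set -0.67, 0.0663), Nsdhl at -0.59 ± 0.15 (0.022), Idi1 at -0.70 ± 0.18 (0.0227) and Dhcr7 at -0.68 ± 0.18 (0.0265). Of 19 hypoxia and glycolysis genes Ndrg1 (-1.79 ± 0.39, 0.00814, a second probe set -1.03, 0.116) and Pfkfb3 (-1.003 ± 0.17, 0.00127, other probe sets -0.73, 0.0697, and 0.16) were lower and 0 higher (12 lower with the block, 4 adjusted over the list alone, adjusted p = 0.000209, estimated-correlation p = 0.42). The Ndrg1 difference was uneven, at -0.66, -0.13 and -0.71 in numbers 1 to 3 and -2.94, -3.22 and -3.07 in numbers 4 to 6. When 1 array was left out, calls were lost (adjusted p in brackets) for Snap25 without BMP array 3 (0.0505) or CNTF array 6 (0.0542) and for Gap43 without BMP array 2 (0.0524) or CNTF array 5 (0.0511). They were also lost for Idi1 without BMP array 1 or 3 (0.0568 and 0.0514) or CNTF array 6 (0.0633). The same held for Nsdhl without BMP array 1 or 3 (0.0518 and 0.0595) or CNTF array 6 (0.0624) and for Dhcr7 without BMP array 1, 2 or 3 (0.0646, 0.0653 and 0.0707) or CNTF array 1, 5 or 6 (0.0506, 0.0675 and 0.072).

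The other 14 lists did not pass for BMP against CNTF. Adjusted p was 0.101 for glutamate uptake (0.0313 without BMP array 6), 0.235 for cyclin-dependent kinase inhibitors, 0.306 for FGF-MAPK feedback, 0.347 for cell cycle (0.0449 without BMP array 3 and 0.0173 without CNTF array 4), 0.39 for astrocyte markers and 0.549 for Notch. The estimated-correlation p of glutamate uptake and cell cycle was 0.42 and 0.898. Adjusted p was 0.59 for neurotrophic factors and for stress, 0.767 for neural stem cells, endothelium and proteoglycans, 0.794 for Schwann cells, 0.949 for microglia and 0.976 for interferon genes. Astrocyte markers had 3 of 24 higher (Slc4a4, Hepacam and Nfib at 1.15, 0.50 and 0.52, with 6 higher and 2 lower adjusted over the list alone), and Notch had Notch2 and Dll4 of 19 (+0.65 and +1.30, with 4 adjusted over the list alone). Among 15 glutamate uptake genes Slc4a4 was higher and Slc1a1 and Slc7a11 lower (-1.40 and -1.75, with 1 higher and 4 lower adjusted over the list alone). Fgf1 was higher (+0.93) and Igf2 and Pdgfa lower (-0.88) among 17 neurotrophic factors, and Ncam1 and L1cam were higher (+0.89 and +1.53) and Pmp22 lower (-0.87) among 12 Schwann cell markers. Atf3 and Asns were lower (-1.66 and -0.43) among 17 stress genes, Myc (-0.51) among 15 FGF-MAPK genes, and Spock1 higher (+2.02) among 19 proteoglycan genes. The remaining 6 of these lists had 0 called members by limma, and 3 of 12 cyclin-dependent kinase inhibitors were lower adjusted over the list alone. At an unadjusted p under 0.05 these lists had 1 interferon gene higher and 1 lower, 3 neural stem cell markers higher and 2 lower, 1 cell cycle gene lower, 3 inhibitors lower, and 0 microglia and endothelial markers. With the block, 3 neural stem cell markers were higher and 2 lower, 1 cell cycle gene was higher and 1 lower, and 2 inhibitors and 1 interferon gene were lower. Higher and lower members with the block were 9 and 3 for astrocyte markers, 5 and 1 for Notch, 1 and 4 for glutamate uptake and for stress, 3 and 1 for FGF-MAPK feedback and 4 and 3 for proteoglycan genes. Slc1a3, Nes, S100b and Ncan differed by -0.59 ± 0.17, -0.48 ± 0.22, 0.41 ± 0.35 and 0.68 ± 0.32 and were not called (adjusted p = 0.051, 0.254, 0.65 and 0.284). Each was called with the block (0.00496, 0.016, 0.0453 and 0.0357). Without CNTF array 1 the differences of Nes and S100b were -0.31 and 0.21, and S100b was at 0.27 without CNTF array 4 and at 0.62 and 0.23 without BMP array 4 and 6. Slc1a3 was also called without BMP array 1 (0.0443), BMP array 4 (0.0101) or CNTF array 3 (0.0292). Id1, Id3, Dcn and Mki67 differed by 0.02 ± 0.30, -0.04 ± 0.26, -0.12 ± 0.32 and 0.21 ± 0.72 (adjusted p of at least 0.919). When 1 array was left out, Id1 ranged from -0.15 (without CNTF array 3) to 0.25 (without BMP array 3), Id3 from -0.18 (without CNTF array 3) to 0.11 (without BMP array 2), Dcn from -0.32 (without CNTF array 1) to 0.09 (without BMP array 1) and Mki67 from 0.00081 (without CNTF array 6) to 0.51 (without BMP array 3). In all, limma called 1934 probe sets between the additions, 1005 higher with BMP and 929 lower, 782 of them by at least 2-fold (421 and 361), and 4686 with the block, the 1934 among them in the same direction. The count was 1111, 1214 and 1190 without all arrays of number 2, 3 and 5, settings added later like those above.

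BMP and CNTF shared part of their calls against the controls. In both comparisons 141 probe sets were higher and 48 lower, 189 in all, and 11 were called in opposite directions. With the block 928 were shared. Independent lists of these sizes would share 16.9 and 5.89. Simulated unchanged groups against the same controls gave at most 1 call in a comparison, so the 0 calls they shared say nothing about these counts. When each addition was compared with its own 3 of the 6 controls, a mean of 32.4 higher (range 16 to 57 over 20 splits) and 4.35 lower calls (1 to 7) were shared. Independent lists of the sizes called there would share 3.77 and 0.941, below the shared count in 20 of 20 splits in both directions. The splits reuse the same arrays and are not 20 separate tests. Both expectations for independent lists take every probe set as equally likely to be called. They are too low where dim or variable probe sets are seldom called. Across probe sets, which are not independent replicates, the log2 differences of the additions correlated with Pearson r = 0.415 and Spearman rho = 0.425, against 0.499 and 0.460 for simulated unchanged groups. With split controls r was 0.185 and rho 0.104, and with separate title numbers for each addition as well they were 0.228 and 0.163. The covariance was 0.0547 against 0.0165 simulated, a difference of 0.0383. With split controls it was 0.0286, and 0.0377 with separate numbers. The overlap fell to 123 without control 2, and to 56, 79, 93 and 118 without all arrays of number 2, 3, 5 and 6. The labels give no time for the controls, and a different time or handling of them would move both additions alike. Splitting the controls cannot test this, since every part consists of controls. It stays open as a source of shared calls.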

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

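The split counts below and the test of the control arrays were fixed beforehand; the test of exchanged labels and the tests on Igf2, H19 and Spp1 and on the fibroblast genes were chosen after the results were seen.

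For each named gene and array measure, the array farthest from the other 5 of its group was compared with the range of that group. The array stood apart in 25 of 297 groups, where about 1 in 20, or 14.85, is the rate without any cause. The array with number 1 lay below the other 5 of its group for the following genes: Mbp at 13.68 in control 1 (others 15.90 to 16.30), 9.33 in BMP array 1 (13.59 to 14.95) and 14.65 in CNTF array 1 (16.23 to 16.51); Cldn11 at 11.31, 8.54 and 13.09 in the same 3 arrays; Gal3st1 at 10.64 in control 1 and 10.58 in CNTF array 1; Myrf at 11.11 and Lamb2 at 10.61 in control 1; the phosphatase Dusp15 at 8.48 in BMP array 1; and Gfap at 15.78 in CNTF array 1. Also low were Insig1 in control 4 (14.20), Slit1 in CNTF array 4 (8.91), Nbl1 in CNTF array 6 (11.27) and Cebpd in BMP array 4 (8.58). High were Cspg4 in BMP array 6 (10.65) and CNTF array 6 (11.14), Ugt8 in BMP array 6 (12.12, 12.125 before rounding), Pnlip and Slc1a1 in CNTF array 6 (14.74 and 13.20), Col6a2 in BMP array 2 (11.13), Cd14 in control 5 (8.92), Aspg in BMP array 4 (7.32), and the GAPDH 3'/5' log2 ratio in BMP array 5 (0.191). What set these arrays apart was not tested.

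Chance assignment of the arrays was set against the counts by drawing 100 of the 462 splits of 12 arrays into 6 and 6. For probe sets changed, the real split was the only 1 of 100 with a count as large in each comparison. That makes chance unlikely and does not exclude it. Counts were 1865 against at most 405 for BMP against control, 721 against 499 for CNTF against control and 1934 against 482 for BMP against CNTF. At 2-fold or more the real split was again 1 of 100 each time (743 against 166, 353 against 228 and 782 against 229). The number of gene lists that passed did not set the real split apart: 7 of 100 splits gave at least the 11 lists of BMP against control (highest other 13), 85 at least the 3 of CNTF against control (highest other 11) and 7 at least the 11 of BMP against CNTF (highest other 13). Against control, no other drawn split gave as small a camera p for gp130-STAT3 targets with CNTF (3.8e-21, smallest other 3.5e-11). The same held for reactive astrocyte genes with either addition and for cholesterol genes with BMP. With BMP, 28, 20 and 7 of 100 splits, the real 1 included, gave as small a p for neuron, hypoxia and oligodendrocyte markers. It was 9 for axon guidance, 7 for glutamate uptake, 4 for BMP-SMAD targets, 3 for precursor markers and 2 each for fibroblast and matrix genes. With CNTF, 6 did so for cholesterol genes. Between BMP and CNTF, 29 did so for neuron markers, 26 for hypoxia, 20 for fibroblast markers and 7 for matrix genes. For the other lists that passed there it was at most 5. Among the 32 splits that part every same-numbered pair, the highest other count was 1, 1 and 3 without the block, and 2, 0 and 220 with it against 5176, 2349 and 4686; other splits leave some pairs in 1 group, so that differences between numbers enter them.

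The BMP effect was larger in some numbers than in others. The slope of each number's BMP minus control difference on the effect in the other 5 numbers, over probe sets called there at 2-fold or more with the block, was 1.21, 1.23, 1.09, 0.65, 0.60 and 0.60 for numbers 1 to 6, and 0.77, 1.09, 1.06, 0.82, 0.92 and 0.88 for CNTF. Differences among the control arrays held 16.1% of the slopes' deviation (9.06 to 19.5 with each number left out), which argues against the controls as its main source. The lowest slope was 0.601, which argues against BMP and control labels exchanged within a number, since that would give a negative slope. Partial mixing of material, a weaker dose and a difference of the source material between numbers could each leave such slopes and stay open.

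Igf2, H19 and Spp1 rose with CNTF by 6.36, 5.73 and 7.02 log2. Added fibroblast or smooth muscle cells would raise their markers too. Of the 8 of 17 markers above the table median in the controls, the largest difference was 0.90 (Tagln, -0.64 to 2.43 within 2 standard errors). A marker that the controls already expressed moves less with added cells than a gene that was dim there. These 8 markers therefore cannot decide, and such cells stay open as a source. For microglia or macrophages no sign was seen: their 17 markers stayed at 7.18 to 9.06 with CNTF, where Spp1 reached 16.62, and differed by at most 0.197 (Fcgr2b). None lay above the median, and how bright these probe sets would be in such cells is not known from the tables, so this source was not excluded. Another transcript read by the Igf2 probe set stays open as well: the other 3 Igf2 probe sets differed by at most 0.164, but lay at 7.21 to 7.74, near the floor. The unknown time of the controls stays open for a part of these rises. BMP and CNTF arrays carry the same time in their labels, and Igf2 and Spp1 differed between them by -3.6 and -5.02. A response of the cells to CNTF is a hypothesis.

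With BMP, 3 of 17 fibroblast and 5 of 21 matrix genes rose (estimated-correlation p of the lists 0.158 and 0.095). A lower share of the oligodendrocyte lineage would raise by a similar amount only genes that this lineage does not express. Among the 23 of 38 genes above the table median, the differences spread over 2.75 log2, from -0.15 (Plod2) to 2.61 (Col1a2). Their median standard error was 0.276. How much of each gene's signal came from that lineage is not known, so the spread cannot decide and that share stays open. Fibroblasts in the BMP arrays stay open: their markers Dcn and Lum reached at most 7.96 there, a level too near the floor to decide. A response to BMP is a hypothesis.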

How the results depend on the processing

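Leaving out all 3 arrays of 1 number was chosen after seeing the data; the other alternatives were planned.

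The counts of probe sets, their overlap and the correlation of both effects stayed within 1.5 times, or within their spread, with quantile normalization, a common 75th percentile, dim or cross-hybridising probe sets left out, no intensity trend, and only the compared groups fitted. With the block, limma called 5176 probe sets for BMP against control, 2349 for CNTF against control and 4686 for BMP against CNTF, and 928 were shared; the block takes the differences between numbers out of the spread. With the constant at the median, which shrinks differences by construction, 321, 144 and 330 changed at least 2-fold. The correlation was 0.456 with a constant of 1, 0.388 with the constant at the median and 0.442 with array weights, and 0.383 (without CNTF array 3) to 0.462 (without control 5) with 1 array left out; the overlap was then 123 (without control 2) to 226 (without CNTF array 1). The cause was not tested.

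Without all arrays of number 2, the calls were 740 (407 at least 2-fold), 389 and 1111 in the same order of comparisons, the overlap 56 and the correlation 0.377. Without number 3 they were 1008, 420 and 1214 with an overlap of 79. Without number 5, CNTF against control gave 366 and BMP against CNTF 1190, with an overlap of 93 and a correlation of 0.443. Without number 6, CNTF against control gave 406, with an overlap of 118 and a correlation of 0.441. The cause was not tested. Without number 1 or 4, all of these stayed within the limits.

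With the correlation estimated from the data, 22 of the 75 list tests lost their call, since camera then allows for genes of a list that vary together. For BMP against control the adjusted p became 0.0835 for reactive astrocyte, oligodendrocyte precursor and cholesterol genes, 0.0950 for matrix, 0.121 for BMP-SMAD targets and oligodendrocyte markers, 0.158 for fibroblast markers and glutamate uptake, 0.163 for axon guidance, 0.325 for neuron markers and 0.342 for hypoxia. For CNTF against control it was 0.715 for cholesterol genes. For BMP against CNTF it was 0.105 for precursor and oligodendrocyte markers, 0.121 for reactive astrocyte genes, 0.149 for BMP-SMAD targets, matrix, axon guidance and cholesterol, 0.354 for fibroblast markers and 0.420 for neuron markers and hypoxia. The gp130-STAT3 targets (CNTF against control and BMP against CNTF) and the reactive astrocyte genes (CNTF against control) kept their calls. With the block and an estimated correlation, oligodendrocyte markers also passed for BMP against CNTF (0.0309), and the lists below that gained a call with the block did not (0.558 to 0.705).

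Some lists gained a call. For BMP against control, gp130-STAT3 targets passed with dim probe sets left out (0.0175) and with the mean of all probe sets (0.0383), and ranged from 0.0197 to 0.159 with 1 array left out; cell cycle genes passed with the block (0.00367), quantile normalization (0.0249) and dim probe sets left out (0.0403), and ranged from 0.000651 to 0.869. With an estimated correlation and no other change, the adjusted p of these lists was 0.325 and 0.810. For CNTF against control, interferon genes passed with dim probe sets left out (0.0234; 0.904 with an estimated correlation and all probe sets), and with the block oligodendrocyte markers (0.0401), hypoxia and Notch (0.0480 each; adjusted p 0.705, 0.705 and 0.558 with the block and an estimated correlation). With 1 array left out, that comparison gave 0.0158 to 0.790 for oligodendrocyte markers, 0.0159 to 0.337 for Notch, 0.0375 to 0.407 for fibroblast markers and 0.0187 to 0.997 for cell cycle genes (adjusted p 0.904, 0.715, 0.904 and 0.943 with an estimated correlation and all arrays). For BMP against CNTF the ranges were 0.000228 to 0.0527 for neuron markers, 0.0173 to 0.952 for cell cycle and 0.0313 to 0.213 for glutamate uptake (adjusted p 0.420, 0.898 and 0.420 with an estimated correlation and all arrays). The cause was not tested.

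Of 152 gene results, 10 gained a call with the block and none lost it. With 1 array left out, 86 of 1824 lost a call and 10 gained one. Of 78 readings by another probe set of the same gene, 51 kept their side, 18 lost the call, 2 gained one and 7 had the opposite sign: Ugt8 (0.0720 for BMP against control and 0.0771 for BMP against CNTF), Igf2 (-0.153 and -0.0190 for CNTF against control), Fos (-0.314), Gap43 (0.119) and Pfkfb3 (0.164). The probe sets of opposite sign lay at 7.12 (Ugt8) to 7.92 (Pfkfb3) in the controls, near the floor. The cause was not tested.

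Signal over background limits dim genes: log2 differences and fold values near the constant are understated.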

Other observations

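The genes of the first 2 paragraphs and the tests on imprinted genes were chosen after the results were seen.

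The following genes were picked from the called ones, and no list of neuropeptide genes was tested. The fixed list of 20 neuron markers holds none of them. With BMP, 4 of its members rose and 1 fell (camera adjusted p = 0.000845, estimated-correlation p = 0.325). Pnoc, the precursor of nociceptin, rose with BMP by 3.01 ± 0.47 log2 (limma adjusted p = 0.00109, 6 arrays per group), Npy, neuropeptide Y, by 2.41 ± 0.41 (0.00146), Crh, corticotropin-releasing hormone, by 2.23 ± 0.35 (0.000997), and Tac1, the precursor of substance P, by 2.12 ± 0.35 (0.00127). The calcium-binding protein Calb2 rose by 1.93 ± 0.27 (0.00054) and the secreted glycoprotein Reln by 1.87 ± 0.49 (0.0255). Npy, Crh, Pnoc, Tac1 and Calb2 were also higher with BMP than with CNTF (by 2.27, 2.51, 2.22, 1.31 and 1.89; adjusted p = 0.0018, 0.000193, 0.00676, 0.0282 and 0.000271).

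The genes of this paragraph were picked in the same way. Of the fixed lists with inflammatory or antiviral genes, that of interferon genes did not pass with CNTF (1 of 24 called, limma camera adjusted p = 0.32). That of reactive astrocyte genes passed, as given above. Neither list holds Il1r1, Il1r2, Casp4 or Ifitm3. The interleukin 1 receptor Il1r1 rose with CNTF by 3.22 ± 0.37 (adjusted p = 3.07e-05), its decoy Il1r2 by 2.60 (4.92e-06), the inflammatory caspase Casp4 by 3.43 ± 0.37 (1.58e-05) and the antiviral membrane protein Ifitm3 by 4.43 ± 0.58 (0.00017). Il1r1, Il1r2 and Casp4 were lower with BMP than with CNTF (by -1.83, -1.25 and -2.54; adjusted p = 0.00439, 0.00545 and 0.00035), and Ifitm3 was not called there (-1.95, adjusted p = 0.0542). Papss2 was called in opposite directions against the controls, at 1.58 with BMP (0.00765) and -1.85 with CNTF (0.004).

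Igf2 and H19 rose with both additions, by 2.75 and 2.94 with BMP. The unknown time of the controls could move both comparisons alike and stays open. A hypothesis was that imprinted genes in general move with Igf2 and H19. With CNTF, none of 22 other imprinted genes was called by limma (1 higher and 1 lower at an unadjusted p under 0.05). With the block Plagl1 was higher (adjusted p = 0.0343) and Gatm and Nnat lower (0.00153 and 0.0497). Camera in limma gave an adjusted p of 0.985 for them, adjusted over both additions. Their mean difference was 0.0445, with an upper bound of 0.187. That bound comes from the spread between genes, taken as independent, and leaves out the spread between arrays. Some members lay near the floor, where a rise is understated, such as Ins2 and Phlda2 (7.56 and 7.75 in the controls). Within these limits the mean argues against a general rise with CNTF, not against a rise of single members. With BMP, 5 rose (Plagl1, Igf2r, Grb10, Ascl2 and Peg12) and 1 fell (Ndn, -0.61), with a limma camera adjusted p = 0.355 (0.318 with an estimated correlation) and a mean of 0.207 (upper bound 0.477), and the hypothesis stays open there. The block added Dlk1 as higher with BMP (limma adjusted p = 0.0046) and Gatm and Cdkn1c as lower (0.0035 and 0.0044).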
